A study of Mus musculus with 4 samples.

How the data were processed

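Small RNA was sequenced from mouse fetal liver of 2 genotypes, wildtype and a catalytic dead mutant of Ago2 (Ago2 CD), with 2 libraries per genotype. Per the labels' protocols, livers were frozen after dissection, total RNA was extracted with Trizol, and libraries were prepared with the TruSeq small RNA kit following a modified procedure. The series' design text describes the libraries of a genotype as biological replicates. The deposited files hold counts: each lists distinct read sequences with the number of reads that had exactly that sequence, and no normalization had been applied to these counts. The submitters' processing notes name cutadapt, a program that removes adapter sequence, without a version. Trimming settings, read filters, aligner and genome build were not given in the sources used here. Tested on the files themselves, the shortest sequence was 16 nt in each library, and the longest was 50 nt in wildtype replicate 1 and Ago2 CD replicate 2 and 46 nt in wildtype replicate 2 and Ago2 CD replicate 1. Each read length therefore held 1 library of each genotype. Values within these pairs are given beside the pooled values of the arms and hairpins past the threshold. Sequences listed more than once in a file (4152 repeated rows in wildtype replicate 1 and 5617 in Ago2 CD replicate 2) were summed. Reads with an undetermined base, 0.183% to 0.256% of a library, were left out of all matching.

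Reads were matched without mismatch to the 2202 miRNA hairpins of GENCODE vM21 (mouse genome build GRCm38), on the sense strand. The annotation used here gives hairpins but not mature arms, so an arm was the side of the hairpin's midpoint on which the middle of the read lay, as had been fixed for this situation before the data were examined. A read of 18 to 27 nt counted for an arm, arms with the same first 18 nt or with 1 most frequent read inside the other were merged, and reads that still matched several arms (0.0074% to 0.0268% of arm reads) were left out. Names follow the annotation's gene symbols. The arms of mir-486 and of mir-3107, a hairpin on the opposite strand of the same locus, were merged, as were those of mir-299a and mir-299b; they are called miR-486 and miR-299 in the text. Reads that matched no hairpin were compared with hairpins after removal of 1 to 3 nt from the 3' end (tailed reads), then with annotated small non-coding RNAs, and, from 20 nt, with protein-coding and other transcripts. Genomic tRNAs and the ribosomal RNA precursor were not analysed here.

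Arm counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr), Ago2 CD against wildtype, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as threshold. Fold changes are log2 of mutant over wildtype. Standard errors were taken as the fold change divided by the square root of the F statistic. Counts per 1000000 (CPM) were computed with TMM-scaled library sizes. Within-pair fold changes are differences of log2 CPM with a prior count of 2. The ratio of the 3p to the 5p arm was tested with limma 3.58.1 on log2 values with a pseudocount of 0.5, for hairpins with at least 20 reads in every library and at least 10 reads on the minor arm over all libraries. The tailed share of an arm was tested in the same way for arms with at least 200 reads in every library. In all, 12 miRNA lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Lengths of reads on the mir-451a hairpin were compared with an exact permutation test, whose smallest two-sided p with 2 libraries against 2 is 0.333. Intervals of shares are exact Clopper-Pearson intervals at 95%, and a count of 0 was taken to allow up to 3 counts. Reads carried no molecular identifiers, so these intervals and limits cover counting error only. Other software was RNAfold 2.7.2, Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.

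The text names miR-451a and both arms of miR-144 and miR-486, then up to 10 arms per direction past the threshold with both mutant libraries beyond both wildtype libraries and a mean of at least 10 CPM. Where fewer than 5 arms passed in a direction, the list was filled to 5 by the smallest unadjusted p among arms that met the other conditions. For the arm ratio and for tails, up to 10 hairpins and up to 5 arms past the threshold were taken by size of change, filled to 5 in each direction by unadjusted p, and 4 members of any list with a call. This rule, the lists, the tests and most alternatives were fixed before the data were examined. Alternatives were other scalings (DESeq2 size factors, reads on arms, all reads of at least 18 nt, library sizes without miR-451a and miR-486), other tests (DESeq2 1.42.0, limma voom), other filters and read definitions, the replicate number as a block, and leaving out each library. A model with read length as a batch term and tails other than C were added after seeing the data.

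The functions were tested on simulated data. In 10 simulations of the comparison of 581 arms, with 200 arms changed in each, the edgeR test called 7.91% of arms changed by 1 log2 unit, 44.5% of those changed by 2 and 97.9% of those changed by 5, and 3.39% of its calls were unchanged arms. For 235 hairpins, limma called 74% of arm ratios changed by 3 log2 units and 100% of those changed by 8. For the tailed share of 278 arms these values were 55% and 97%. Camera called a list of 10 arms shifted by 1 log2 unit in 10 of 10 simulations and an unshifted list in 0 of 10. The simulated noise was drawn for each arm on its own, without an effect of read length shared between arms or correlation within a list. In the data the estimated correlation within a list reached 0.875 (stem and progenitor). These rates, above all those of camera, need not hold for the data.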

Results

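Small RNAs of mouse fetal liver, the site of red cell formation at this stage, were compared between wildtype and Ago2 CD animals, with 2 libraries each. Ago2 is the Argonaute protein that can cut RNA paired to its guide, and the mutant lacks that activity. The libraries held 15841697 and 13138065 reads in wildtype replicates 1 and 2, and 21875540 and 15238066 reads in Ago2 CD replicates 1 and 2. Of these, 9684935, 9178818, 14423291 and 7814315 reads, in the same order, were of mature size and assigned to a miRNA arm. Fragments of the Ago2 mRNA (chromosome 15, 73095844 to 73184935, minus strand) were found in each library, at 12.9 and 15.8 per 1000000 reads outside the mir-451a hairpin in wildtype and 18.2 and 17.5 in Ago2 CD, a ratio of means of 1.25. Per 1000000 reads of the whole library, which in wildtype holds the reads of mir-451a, the values were 7.70 and 11.04 against 18.1 and 17.5. These fragments do not check the labels, since a point mutation need not alter the amount of mRNA.

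The first question was which miRNAs depend on the cutting activity of Ago2. MiR-451a, the main miRNA of red cell precursors, was found to be 573-fold lower in Ago2 CD fetal liver (log2 fold change -9.16, SE 0.70, edgeR adjusted p = 0.0364, n = 2 per genotype). It had 5018791 and 3677788 reads in the wildtype libraries and 23965 and 9177 in the mutant libraries. Its share of arm reads was 45.9% ± 8.31 (SD, n = 2) in wildtype and 0.142% ± 0.0344 (SD, n = 2) in Ago2 CD. The 3p arm of miR-486, the other strand of a second miRNA abundant in red cells, was 37.2-fold higher in the mutant (log2 fold change 5.22, SE 0.37, edgeR adjusted p = 0.0364). It had 21.7 ± 5.91 CPM (SD, n = 2) in wildtype and 787 and 830 CPM in the mutant libraries, from 15617 and 7856 reads. These were the 2 arms of 581 tested that passed the threshold. Within the libraries of 46 nt and of 50 nt the log2 fold change was -8.43 and -9.74 for miR-451a and 4.92 and 5.55 for miR-486-3p. With read length in the edgeR model, 0 arms passed, with 113 arms at an unadjusted p under 0.05, and the adjusted p of both arms was 0.0765 at log2 fold changes of -9.09 and 5.23. Without Ago2 CD replicate 1 or 2, 0 arms passed in edgeR, with 14 and 9 at an unadjusted p under 0.05, at log2 fold changes of -9.33 and -9.01 for miR-451a and 5.25 and 5.18 for miR-486-3p. Without wildtype replicate 1 miR-486-3p did not pass (log2 fold change 5.01, edgeR adjusted p = 0.0870), miR-215-5p did, and the log2 fold change of miR-451a was -8.54. Without wildtype replicate 2 the muscle arms miR-1a-3p and miR-206-3p passed as well, 4 arms in all. In such fits the genotype left with 1 library is assumed to vary like the other, so the added arms follow the level of 1 wildtype library: miR-206-3p had 128.9 CPM in replicate 1 and 3.06 in replicate 2, miR-1a-3p 209.5 and 16.5 CPM, and miR-215-5p 1.49 and 84.3 CPM.

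**Figure D1:**
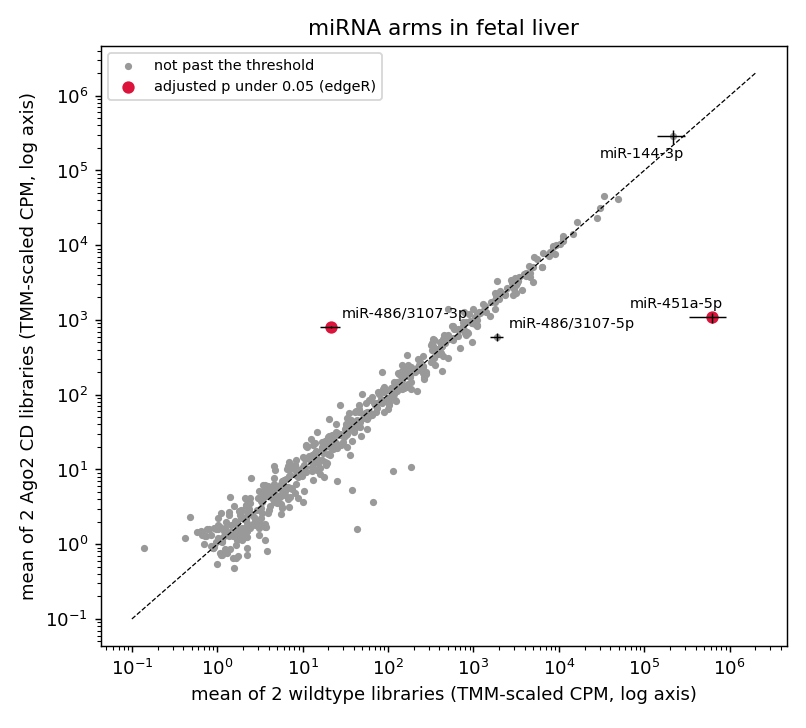
Mean TMM-scaled CPM of each tested miRNA arm in the 2 Ago2 CD libraries (vertical, log axis) against the 2 wildtype libraries (horizontal, log axis), with SD bars on 4 labelled arms and a dashed line of equal values. The arms past the threshold, in red, are miR-451a below the line and miR-486-3p above it.

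The hairpin of mir-451a lies on chromosome 11 (78073170 to 78073241, plus strand, GRCm38), 99 bases downstream of that of mir-144 (78073005 to 78073070, plus strand). A hairpin on the other strand, mir-451b, is annotated at the same bases. MiR-144, the neighbour of miR-451a, is processed by Dicer, and its arms did not pass the edgeR test. MiR-144-3p had 1656875 and 1446051 reads in wildtype and 4820833 and 3102604 in Ago2 CD, or 218919 ± 77543 and 285337 ± 59856 CPM (SD, n = 2). Its log2 fold change was 0.38 (SE 0.44) and ranged from 0.052 to 0.83 on leaving out each library. MiR-144-5p had 14119 and 44155 reads in wildtype and 59887 and 19822 in Ago2 CD, with a log2 fold change of -0.52 (SE 0.48), whose sign turned with reads on arms as library size (0.094) and without wildtype replicate 2 (0.14). The mir-486 hairpin lies on chromosome 8 (23142555 to 23142682, plus strand), between exons of Ank1, the gene of a red cell membrane protein, and mir-3107 lies on the minus strand at 23142573 to 23142662. MiR-486-5p, with 12999 and 14749 reads in wildtype and 10831 and 6109 in Ago2 CD, had 1911 ± 335 CPM in wildtype and 596 ± 70.1 CPM in Ago2 CD (SD, n = 2). Its log2 fold change was -1.68 (SE 0.29), which did not pass (edgeR adjusted p = 0.690) except by DESeq2 (0.0275) and without a filter (0.0375), and was -1.62 and -1.73 within the libraries of 46 and 50 nt.

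The remaining named arms failed the threshold, with an edgeR adjusted p of 0.995 each, and were taken by their unadjusted p. Those with higher values in both mutant libraries were the 3p arms of miR-299 (log2 fold change 1.22, SE 0.32), let-7d (1.02, SE 0.28) and miR-98 (1.08, SE 0.35), and the 5p arm of the mir-103-2 hairpin (1.22, SE 0.37). MiR-299-3p, from chromosome 12 (109710638 to 109710700), had 85.3 ± 15.5 CPM in wildtype and 200 ± 36.4 CPM in Ago2 CD (SD, n = 2). Let-7d-3p, from chromosome 13 (48536012 to 48536114), had 168 ± 18.5 and 342 ± 45.0 CPM. Those with lower values were miR-434-5p (log2 fold change -0.91, SE 0.25), miR-409-5p (-1.05, SE 0.30) and miR-449a-5p (-1.17, SE 0.36). MiR-434-5p and miR-409-5p come, like miR-299-3p with its higher values, from the imprinted Dlk1-Dio3 region of chromosome 12 and had 963 ± 35.7 against 511 ± 2.54 CPM and 432 ± 94.7 against 209 ± 9.57 CPM. These fold changes are relative to TMM scaling, under which the median of all arms was 0.05. With reads on arms or all reads of at least 18 nt as library size the median was 0.74 and 0.57, since library sizes of this kind include miR-451a in wildtype.

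Lists of miRNAs that mark cell types or share an origin were examined next. Of the 11 erythroid arms, miR-486-3p rose, miR-451a fell and 9 did not pass; adjusted over the list alone, 1 was higher and 2 were lower, miR-486-5p being added. The abundant erythroid arm miR-16-5p had a log2 fold change of -0.27, and miR-210-3p had 0.79. None of the other 11 lists held an arm past the threshold, over all arms or adjusted over the list alone. The 8 hepatocyte arms had a median log2 fold change of 0.17, with 0.42 for miR-122-5p, the main hepatocyte miRNA, and 0.16 for miR-192-5p. This median turned to -0.17 without wildtype replicate 1 and -0.38 without Ago2 CD replicate 1, and was 1.26 without wildtype replicate 2 and 0.56 without Ago2 CD replicate 2. The 9 myeloid and lymphoid arms had a median of 0.04, with -0.25 for miR-142-3p and -0.27 for miR-223-3p. For 8 arms of stem and progenitor cells the median was -0.09, for 2 endothelial arms -0.06, for 7 mesenchymal arms -0.10 and for 6 epithelial arms -0.07. The 23 tested arms of the mir-17 to mir-92 clusters, which act in proliferating cells, had a median of 0.07, and the 84 arms of the Dlk1-Dio3 cluster 0.02, with camera's direction down. The 4 tested arms of hairpins made without Drosha had a median of 0.40, which ranged from 0.20 to 0.73 on leaving out each library. The medians of the lists are on the TMM scale too, and with reads on arms as library size those of all lists but neuron and muscle were above 0. Leaving out a library turned the sign of the median of 7 lists (hepatocyte, stem and progenitor, endothelial, mesenchymal, epithelial, mir-17 to mir-92 and Dlk1-Dio3) and kept that of 5.

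The 8 members of the let-7 family had a median log2 fold change of 0.30 and were higher within both pairs of libraries of equal read length; the median ranged from 0.076 to 0.72 on leaving out each library, lowest without wildtype replicate 1 and highest without wildtype replicate 2. By camera 0 of the 12 lists passed, with adjusted p of at least 0.353, and of at least 0.956 with an estimated correlation; 0 lists had an unadjusted camera p under 0.05. By fry 0 lists passed and 1, the mesenchymal, had an unadjusted p under 0.05 (adjusted p = 0.129). With read length in the model the let-7 list passed camera (adjusted p = 0.0104), which was lost with an estimated correlation (adjusted p = 0.885). The 6 arms of neuron and muscle, tissues outside the liver, had a median of -1.87, which was -0.56 and -0.50 without wildtype replicates 1 and 2 and -3.36 and -1.63 without Ago2 CD replicates 1 and 2. In this list the shared 3p arm of miR-133a and miR-133b had 359 CPM in wildtype replicate 1, 11.8 CPM in wildtype replicate 2, and 4.59 and 17.003 CPM in Ago2 CD replicates 1 and 2. MiR-9-5p followed read length instead, with 167 and 217 CPM in the libraries of 46 nt and 10.2 and 13.8 CPM in those of 50 nt.

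The balance of the 2 arms of a hairpin was compared within each library, since cutting by Ago2 can remove the passenger strand of a duplex. Of 235 hairpins, mir-451a and mir-486 had a changed ratio, both toward the 3p arm. For mir-451a, which Ago2 cuts instead of Dicer, the ratio is not a balance of guide and passenger strand. Most of its 3p reads in the mutant spanned the site of that cut, and its 5p arm had a log2 fold change of -9.16. Among reads without a tail, the 3p arm made up 1.17% ± 0.504 of mir-486 reads in wildtype and 57.7% ± 1.97 in Ago2 CD (SD, n = 2). The log2 change of the 3p to 5p ratio was 6.92 (SE 0.57, limma adjusted p = 0.00664). Tailed reads, left out here, made up 53.9% of miR-486-5p reads in wildtype and 65.4% in Ago2 CD, so these are not shares of all mir-486 reads. With tailed reads counted, the log2 change of the ratio was 6.06 (limma adjusted p = 0.0272). The edgeR log2 fold changes were then 4.71 for the 3p arm and -1.31 for the 5p arm. For mir-451a the 3p arm made up 0.0683% ± 0.0489 and 55.3% ± 14.9 of reads without a tail (SD, n = 2), a log2 change of 11.05 (SE 0.80, limma adjusted p = 0.00664). Within the libraries of 46 and 50 nt the changes were 6.54 and 7.29 for mir-486 and 11.23 and 10.87 for mir-451a, and both hairpins passed with read length in the model. Without Ago2 CD replicate 1 or 2, 0 hairpins passed in limma, with 7 and 3 at an unadjusted p under 0.05, at log2 changes of 6.83 and 7.0 for mir-486 and 11.67 and 10.43 for mir-451a. Without wildtype replicates 1 and 2 the changes were 6.46 and 7.38 for mir-486 and 11.85 and 10.24 for mir-451a.

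**Figure D2:**
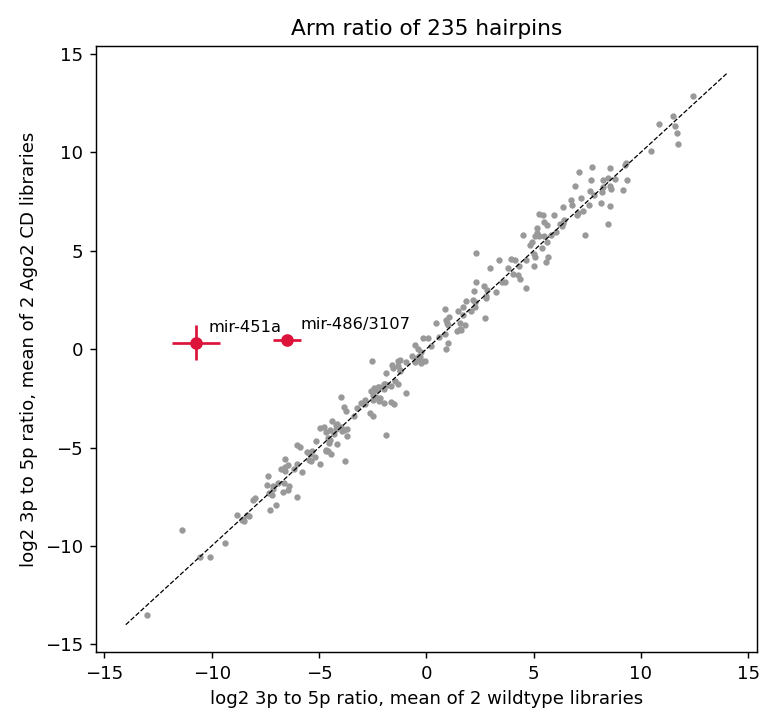
Log2 ratio of 3p to 5p reads for 235 hairpins, mean of 2 Ago2 CD libraries (vertical) against mean of 2 wildtype libraries (horizontal), with the dashed line of equal ratios and SD bars on the hairpins past the threshold. In red, mir-486 and mir-451a lie above the line by 6.92 and 11.05 log2 units.

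The hairpins next by unadjusted p did not pass (limma adjusted p of at least 0.706). Toward the 3p arm these were mir-181d, whose 3p arm had 0 reads in both wildtype libraries and 3 and 7 in the mutant libraries, mir-200a (99.5% ± 0.194 and 99.8% ± 0.00849 from the 3p arm) and mir-299. For mir-299 the 3p share was 14.8% ± 1.74 in wildtype and 39.6% ± 8.25 in Ago2 CD (SD, n = 2), a log2 change of 1.91. Toward the 5p arm they were mir-574, with a 3p share of 21.3% ± 2.84 and 4.96% ± 2.60 (SD, n = 2), mir-1839 (26.2% ± 3.99 and 12.6% ± 0.625), mir-328 (99.8% ± 0.226 and 98.9% ± 0.308), mir-301b (99.4% ± 0.0742 and 98.3% ± 0.142) and mir-100 (1.38% ± 0.0240 and 0.556% ± 0.501).

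The hairpin of mir-451a is cut by Ago2 instead of Dicer, after guide nucleotide 30, and the product is then shortened. The 5' end of the mature miRNA lies at hairpin position 17 (chromosome 11, base 78073186). Its most frequent read in wildtype was AAACCGTTACCATTACTGAGTTT (23 nt), with 1999749 and 1302138 reads in wildtype and 2560 and 1444 in Ago2 CD. Reads of 28 to 30 nt from this 5' end numbered 274957 and 95344 in wildtype and 184 and 60 in Ago2 CD. Reads that spanned the cut after position 46 were more frequent in the mutant, with 150 and 135 in wildtype and 20808 and 19870 in Ago2 CD. Per 1000000 reads outside the hairpin these were 15.2 ± 0.802 and 1130 ± 250 (SD, n = 2). In the mutant most of them started at positions 31 to 40 and ended at position 57 (base 78073226), with 114 and 34 such reads in wildtype and 14094 and 15359 in Ago2 CD. An example is GAGTTTAGTAATGGTAACGGTTCT, with 1 read in each wildtype library and 3662 and 1956 reads in the mutant libraries. The 20 nt read AAACCGTTACCATTACTGAG was the most frequent hairpin read of both mutant libraries, with 6368 and 3714 reads, against 9070 and 183673 in wildtype.

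**Figure D3:**
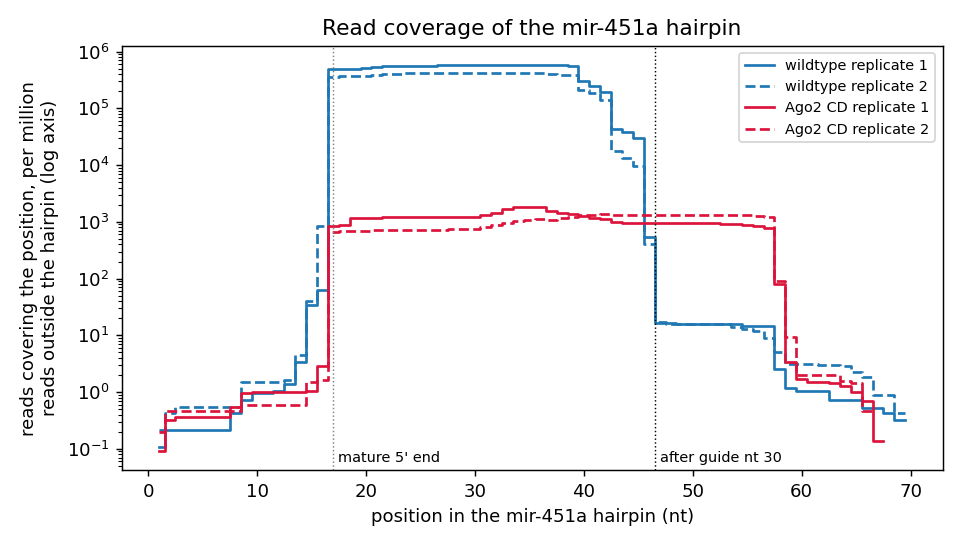
Reads that cover each position of the mir-451a hairpin (horizontal, nt) per 1000000 reads outside the hairpin (vertical, log axis), for the 4 libraries, with dotted lines at the mature 5' end and after guide nucleotide 30. Wildtype coverage falls steeply near the cut, to 16.2 and 17.1 at position 47 in replicates 1 and 2, and goes on at a low level to position 57. In Ago2 CD replicates 1 and 2 it was 953 and 1307 at position 47 and 765 and 1215 at position 57.

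Reads of mature size, 18 to 27 nt, made up 91.9% (95% interval 91.9% to 91.9%) and 95.001% (94.98% to 95.02%) of the hairpin's reads in wildtype replicates 1 and 2, and 91.3% (91.1% to 91.6%) and 86.5% (86.1% to 86.9%) in Ago2 CD replicates 1 and 2. The means of 93.5% and 88.9% differed by -4.53 percentage points (exact permutation p = 0.333, the smallest this design allows, so no call was made). The difference was -6.07 and -2.99 without wildtype replicates 1 and 2, and -6.94 and -2.12 without Ago2 CD replicates 1 and 2. In the mutant this size class is not only miR-451a, since most reads that spanned the cut were 3' fragments of 18 to 27 nt. Reads that spanned the cut, of any length, made up 43.8% and 64.1% of the hairpin's reads in Ago2 CD replicates 1 and 2. In wildtype replicates 1 and 2 they made up 0.00274% and 0.00349%. Shares of mature size therefore do not show how much of the hairpin was processed. Reads of precursor size, 38 nt or longer, numbered 30 of 47500 in Ago2 CD replicate 1 (0.0632%, 95% interval 0.0426% to 0.0902%) and 0 in the other libraries. A count of 0 allows a share of up to 5.49e-05%, 7.75e-05% and 0.00967% in wildtype replicates 1 and 2 and Ago2 CD replicate 2.

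The share of reads with untemplated 3' nucleotides was compared for 278 arms. By limma 0 arms passed and 0 had an unadjusted p under 0.05. Over all arms the tailed share was 16.9% and 22.1% in the libraries of 50 nt and 6.83% and 8.73% in those of 46 nt. An added C made up 12.8% and 16.3% in the former and 0.126% and 0.149% in the latter. Each genotype had 1 library of each kind, so this difference widened the spread within genotypes. The test without read length could therefore hardly call an arm, and its lack of calls says little about tails. The arm first by unadjusted p was miR-299-5p, tailed in 8.71% ± 5.83 of its reads in wildtype and 19.2% ± 2.19 in Ago2 CD (SD, n = 2). MiR-486-5p was tailed in 53.9% ± 5.33 and 65.4% ± 1.94, and miR-574-5p, miR-451a-3p and miR-485-3p followed, with 22.6% ± 1.37 and 28.8% ± 8.48, 7.48% ± 3.41 and 12.8% ± 10.2, and 25.9% ± 2.66 and 29.95% ± 2.80. With lower values in the mutant were miR-93-3p (25.4% ± 2.59 and 18.1% ± 2.91), miR-1193-3p (18.3% ± 0.409 and 13.2% ± 0.472), miR-501-3p (25.3% ± 4.29 and 18.5% ± 4.13), miR-185-5p (31.1% ± 2.05 and 23.98% ± 2.47) and miR-30a-3p (44.4% ± 4.06 and 37.3% ± 6.37). None of these passed (limma adjusted p of 0.999 each). With read length in the model 2 arms passed, miR-299-5p (limma adjusted p = 2.73e-09) and the 5p arm of one mir-24 hairpin (0.00702), with log2 changes of the tailed to templated ratio of 1.49 and 0.86. Counting tails of 1 nt other than C, with read length in the limma model, 0 of 264 arms passed, with 35 at an unadjusted p under 0.05. For miR-299-5p such tails made up 1.88% and 2.46% in wildtype replicates 1 and 2 and 8.05% and 5.89% in Ago2 CD replicates 1 and 2, a log2 change of 1.74 (SE 0.084, limma adjusted p = 0.136), against 1.49 (SE 0.21) for all tails. The change was thus no smaller, and the call ended with the degrees of freedom of the test, 2.66 in place of 278 for all tails, where limma took 1 variance for all arms. The mir-24 arm was not among the 264.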

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

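The comparison of RNA classes outside the miRNA arms, and the tests on miR-451a reads and on miR-486-3p (except the share of mir-3107 among reads that tell the hairpins apart), were chosen after the results were seen, and the bound of the test on reads of 23 to 26 nt was changed after its first outcome. Among reads outside the mir-451a hairpin, 6 of 10 classes that the comparisons do not use were higher in both mutant libraries than in both wildtype libraries. The ratio of the mutant to the wildtype mean was 1.5 for fragments of protein-coding transcripts, 1.99 for mitochondrial tRNA, 1.64 for mitochondrial rRNA, 1.34 for snRNA, 1.36 for other small structural RNAs and 1.32 for other annotated transcripts. In the other 4 the groups overlapped, with 4.75 for rRNA (0.0145% and 0.00169% in wildtype replicates 1 and 2, 0.00161% and 0.0753% in Ago2 CD replicates 1 and 2, so carried by 1 mutant library), 1.28 for scaRNA, 0.921 for snoRNA and 0.822 for reads without a match, the largest class, which made up 37.2% and 28.6% in wildtype replicates 1 and 2 and 22.7% and 31.5% in Ago2 CD replicates 1 and 2, lower in the mutant within both pairs of equal read length. Protein-coding fragments made up 0.620% ± 0.0715 in wildtype and 0.930% ± 0.0848 in Ago2 CD (SD, n = 2). For a class whose groups do not overlap the exact permutation p is 0.333, the smallest that 2 libraries against 2 can give.

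Reads of the mir-451a hairpin that remained in the mutant were weighed against carry-over from wildtype libraries. Among reads from the mature 5' end, the ratio of 20 nt to 23 nt reads was at least 2.49 in the mutant libraries and at most 0.141 in wildtype, so carry-over does not account for the 20 nt reads. For reads of 23 to 26 nt, the bound used first, a share outside the wildtype range in both mutant libraries, was passed by 2 of the 4 lengths, 25 nt (24.5% and 14.7% against 10.1% and 13.4%) and 26 nt (27.99% and 20.5% against 29.1% and 32.2%), which speaks against carry-over. The range of 2 libraries is narrow, and under a stricter bound set after that, past the range by more than its width, 0 lengths passed, so carry-over and residual processing cannot be told apart there. Reads that cross the cut were at least 60.3 times as frequent in a mutant library as in a wildtype library, consistent with a precursor that was not cut. This is a hypothesis, since whole precursors were hardly seen. Reads of 38 nt or longer numbered 30 in Ago2 CD replicate 1 and 0 in Ago2 CD replicate 2. Reads of such size were rare in these libraries whatever their origin. Each length from 38 to 43 nt made up 0.0063% to 0.0376% of Ago2 CD replicate 1 and 0.0037% to 0.0101% of replicate 2. The scarcity of whole precursors therefore does not speak against the hypothesis.

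For the rise of miR-486-3p, 3 technical explanations were set against a loss of passenger strand cutting. Reads that only mir-3107 gives were 0.288% and 13.6% of the reads that tell the hairpins apart in Ago2 CD replicates 1 and 2. In wildtype replicates 1 and 2 they were 3.13% and 0%, from 2 and 0 reads. Ago2 CD replicate 2 alone thus lay above the bound of 10% set beforehand. That bound was missed, and the verdict rests on a test added after it: reads that only mir-486 gives were higher by at least 4.93 log2 units in the pairs of equal read length, so mir-3107 does not account for the rise as a whole, though its part in that library stays open. Scaling left a log2 fold change of at least 5.15 and read length one of at least 4.92, so neither accounts for the rise. A passenger strand that is not cut stays open and untested by these values: the 3p to 5p ratio, at least 6.38 log2 units higher in a mutant than in a wildtype library, is part of the pattern itself, and other hairpins paired at guide positions 9 to 12 showed no gain that could support it (one-sided permutation p = 0.576).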

How the results depend on the processing

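Of 285 values of 20 results under alternative settings, 254 were counted as unchanged. These kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the count. An exception is the share of mir-451a reads of precursor size, counted as unchanged though its difference went from 0.0316 percentage points to 0 without Ago2 CD replicate 1. Most of the 254 belong to arms that failed the threshold in the main analysis and failed it again. The tally therefore does not measure how firm the calls are. An equal count need not hold the same arms: without wildtype replicate 1, and with reads of 20 to 24 nt from the most frequent start, the 2 arms called included 1 of the 2 of the main analysis. The scalings, limma voom, tails, split reads and the filter of at least 10 CPM gave 2 changed arms as in the main analysis, miR-451a and miR-486-3p. DESeq2 called 6 arms and no filter called 11, both including these 2 and muscle arms; leaving out each library gave 0 to 4. Reads of 20 to 24 nt starting at the most frequent position gave 2 arms, miR-486-3p and, higher in the mutant, miR-451a-3p; miR-451a-5p did not pass (-8.998, adjusted p = 0.0844, within 8.21e-57 to 0.526 over its alternatives). The numbers did not pair the samples: same-numbered libraries had deviations with a correlation of -0.72 across arms, and those of equal read length 0.72. With 2 libraries per genotype the deviations from their mean mirror each other, so the second value is the first with its sign turned and no separate observation. With the replicate block 2 arms and 2 hairpins were called, 0 arms had a changed tailed share and 1 list passed. The crossed pairing, which equals read length and was chosen after seeing the data, gave 0 arms, 2 hairpins, 2 arms with a changed tailed share and 1 list. For lists, reads on arms and all reads of at least 18 nt as library size also gave 1, and leaving out each library gave 0 to 1; except for let-7 with read length, the list was neuron and muscle, and none held with an estimated correlation. Hairpins with a changed arm ratio ranged from 0 to 2 on leaving out each library. MiR-144-5p, not past the threshold, changed sign to 0.094 with reads on arms as library size, and ranged from -0.92 to 0.14 on leaving out each library. Without either mutant library 0 arms and 0 hairpins passed, and the cause was not tested; each of these fits sets 1 library against 2, takes its spread from the genotype with 2, and assumes that the lone library varies like them. With 2 libraries per genotype, changes of 1 log2 unit were mostly beyond reach.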

Other observations

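The tests in this part, except that of pairing at guide positions 9 to 12, were chosen after the results were seen, as were the bootstrap intervals used to read the tests of hairpins. Fragments of liver and red cell mRNAs were present in the small RNA libraries. Counted per 1000000 reads outside the mir-451a hairpin, fragments of Alb (albumin) numbered 70.8 and 127.4 in wildtype and 226 and 164 in Ago2 CD, those of Afp (alpha-fetoprotein) 43.1 ± 11.8 and 83.1 ± 0.569, and those of the adult beta globin gene Hbb-bs 135 ± 27.2 and 184 ± 7.91 (SD, n = 2). The ratios of means were 1.97 for Alb, 1.93 for Afp and 1.37 for Hbb-bs. On the same scale protein-coding fragments as a whole had 1.5, mitochondrial tRNA 1.99 and mitochondrial rRNA 1.64. The other hepatocyte mRNAs counted, from fewer reads, had 2.11 for Apoa2, 2.06 for Ttr and 1.38 for Apoa1. Hbb-bs lay below protein-coding fragments as a whole and the alpha globin gene Hba-a1 (1.53) close to them, so these values do not single out red cell mRNAs. Whether liver mRNAs rose beyond other RNA was not tested. The embryonic globin Hbb-y had 8, 3, 7 and 26 reads in wildtype replicates 1 and 2 and Ago2 CD replicates 1 and 2. MiR-215-5p, chosen after its values were seen, had 84.3 CPM in wildtype replicate 2 and at most 2.11 CPM in the other libraries, and miR-802-5p had 73.6 CPM there and at most 7.41 CPM elsewhere. MiR-124a-3p had 64.5 and 56.5 CPM in the libraries of 46 nt and 0.496 and 0.634 CPM in those of 50 nt.

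Muscle arms were high in wildtype replicate 1 alone, as given for the 3p arm of miR-133a and miR-133b. In the mutant library of the same read length this arm had 4.74% of that level, so read length does not account for it. Of 12 muscle mRNAs, fragments numbered 6 in wildtype replicate 1 and 0, 1 and 1 in the others (two-sided Fisher's exact p = 0.00336), but 4 of the 6 came from Ttn, and reads of 1 mRNA without molecular identifiers are not independent. With each gene counted once, 3 of the 12 had a read in wildtype replicate 1 and 0, 1 and 1 in the others (two-sided Fisher's exact p = 0.0918), so too few fragments were found to tell whether that sample held muscle RNA. No biological explanation was tested.

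A hypothesis was that hairpins other than mir-486 also gain their minor arm when Ago2 cannot cut. Over 233 hairpins without mir-451a and mir-486, the median log2 change of the minor over the major arm was -0.01 (-0.0076, bootstrap 95% interval -0.09 to 0.08). It was higher in 115 and lower in 118, so no general gain was seen in these libraries. Within both pairs of equal read length, 77 hairpins were higher and 84 lower. The bootstrap and permutation tests here take hairpins as units, so they leave out variation between the 2 libraries of a genotype. A second hypothesis was that duplexes paired at guide positions 9 to 12, where Ago2 cuts, gain more. For 88 hairpins paired there in the RNAfold structure and the others, without mir-451a, the medians differed by -0.006 (bootstrap 95% interval -0.25 to 0.17, one-sided permutation p = 0.5405). A median at or below that of the others had been set beforehand as evidence against this hypothesis; it was met, but by less than the interval, and on that ground, taken after the result was seen, the question is left open. For the 15 hairpins with guide nucleotides 2 to 18 all paired the median was higher by 0.19 (bootstrap 95% interval 0.026 to 0.65, which leaves out 0; one-sided permutation p = 0.124), and without mir-486 by 0.17 (-0.021 to 0.52; one-sided permutation p = 0.160), so a gain in such hairpins beyond mir-486 is neither shown nor excluded.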
